A study of Mus musculus with 6 samples.

How the data were processed

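Liver RNA of male mice was measured on 6 Affymetrix mouse Gene 1.0 ST arrays, 2 arrays in each of 3 groups. Per the labels' protocols, total RNA was extracted with ISOGEN from homogenised liver and biotin-labelled with the GeneChip WT Terminal Labeling kit. The groups follow the labels' source names, which give the genotype and the supply of ascorbic acid (AA, vitamin C). The deposited values, taken here as log10, form one table with a column per array. The software, background correction, summarisation, normalisation and log base behind these values are not given in the sources used here. The values ran from -0.58 to 2.51, a span of 8.48-fold if they were log2, 21.8-fold if natural log and 1213-fold if log10. The log10 reading is therefore used for every fold printed, and differences are printed in the deposited log units, which need no such choice. A fold on another base would be smaller. The p-values do not depend on the base.

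The median of the values was between 0.350 and 0.392 on each array and the quantiles differed between arrays, so the deposited values did not share a common distribution. Whether quantile normalisation was applied at an earlier step, before summarisation, is not known here. Genes were not centred. Of 34760 probe sets, 3995 held no value on any array and were left out. No detection call or background value was used here, so a low value cannot be separated from background, and no lower bound on a fold is given. The number of arrays limits the precision of every value.

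Probe sets were named through the platform annotation. Of the 30765 probe sets with a value, 21161 had exactly 1 gene symbol, 1150 had several and 8454 had none. Entrez identifiers of 21079 of the named probe sets matched the RefSeq gene table (GRCm38.p6), and 0 symbols needed an update. That table served only for names and for the span of each gene in the genome, introns included. No genome sequence was used. Genes were represented by probe sets with 1 symbol, and for the 925 genes with more than 1 probe set the one with the highest mean over the 6 arrays was taken, which left 19550 genes. Genes with a mean at or above the 25th percentile (a value of 0.185) were tested, 14662 in all.

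Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes without trend or robust options), with all 6 arrays in one fit. The 3 groups thus shared 1 estimate of the spread, with 3 residual degrees of freedom and 4.89 prior degrees of freedom. P-values are two-sided, were adjusted by the Benjamini-Hochberg method over the genes tested within a comparison, and passed at an adjusted p under 0.05. The design had been written for log2 or linear values. Since the values proved to be on a log scale already, limma was run on them as deposited, with no pseudocount.

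Before the data were examined, the design, most alternatives and 36 gene lists (pathways, cell types and the neighbours of Rgn on the X chromosome) were fixed, together with the rule for the genes named. Of 635 list entries, 568 were matched to a gene with a value and 26 lay only on probe sets shared by several genes. The erythroid list was not tested because its globin genes lay on such shared probe sets, and 35 lists were tested. Each list was tested with camera from limma at its preset correlation between genes of 0.01, adjusted over the lists within a comparison. Camera with an estimated correlation and fry were run beside it. For each list, the number of members past the threshold was also counted with p adjusted over the list alone. In each comparison 0 lists passed with an estimated correlation.

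The named genes in each comparison were Rgn and Gulo, the 12 largest rises and the 12 largest falls among genes past the threshold whose groups did not overlap, up to 4 members of smallest p from each list past camera, and up to 3 members of 9 metabolic and acute phase lists. The 10 genes of largest mean change shared by both comparisons of the AA-deficient knockouts were added. Symbols of predicted genes, Rik clones, receptors of the Olfr and Vmn families, small RNAs and bare accessions were left unnamed but stayed in all counts. Where under 24 genes passed, all named ones that passed were eligible, and genes of smallest p that did not pass filled up to 10.

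The fit was tested on simulated data of the same 14662 genes for the comparison of AA-deficient with AA-supplemented knockouts, with 200 genes changed in each of 20 runs. It recovered 4.33% of genes changed 1.5-fold, 55.0% of those changed 2-fold and 98.0% of those changed 4-fold, on the log10 reading. Of its calls, 5.35% were false. The simulated spreads were drawn from limma's own fitted prior, alike in every group and unrelated to the mean value, with arrays drawn independently. In the data, replicate differences had an SD of 0.104 in AA-supplemented knockouts against 0.079 in each other group. These rates therefore hold for data that meet the fit's assumptions and do not measure its error rate on these arrays. A shift of 0.1 given to the cholesterol synthesis list was recovered in 100% of the runs. The simulated genes were drawn independently of each other, while the estimated correlation within this list was 0.434 in the data. The recovery therefore does not test camera at its preset correlation on genes that move together. The alternatives tried were no filter or a stricter filter on dim genes, quantile normalisation, centring on the median, eBayes with a trend or with a trend and robust fit, array weights, the mean of a gene's probe sets, only the 4 arrays compared, the replicate number as a block, camera with an estimated correlation, fry, and leaving out each array. Removal of the trend on gene span, cyclic loess normalisation and a crossed block were chosen after seeing the data. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.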

Results

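The study compared liver transcripts of mice lacking SMP30/GNL with those of wild-type mice of the same background. SMP30 (senescence marker protein 30, also regucalcin) is the gluconolactonase that mice need to make AA, and its gene is Rgn. The labels describe male mice of a C57BL/6 substrain in 3 groups of 2 arrays. The first group were knockouts on a diet without AA (AA-deficient). The next were knockouts given AA in EDTA-stabilised drinking water at a level that keeps tissue AA normal (AA-supplemented), and the last were wild type on the diet without the vitamin. The series asks how the loss of SMP30 and of AA acts on the liver transcriptome and lipid metabolism. Across all probe sets with a value, the arrays of one group correlated at 0.973 in AA-deficient knockouts, 0.965 in AA-supplemented knockouts and 0.975 in wild type, and arrays of different groups at 0.945 to 0.974. Nothing in the labels says that the arrays of a group came from separate animals beyond their being separate samples. The p-values therefore measure only the spread between these samples, which may be technical. Group values below are means ± SD in deposited log units (n = 2), and differences carry their standard error (SE). Folds hold on the log10 reading of the values.

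Rgn (Entrez 19733, probe set 10598863) had a value of 2.03 ± 0.052 in wild type (SD, n = 2), 0.24 ± 0.14 in AA-supplemented knockouts and 0.26 ± 0.049 in AA-deficient knockouts. It fell by 1.79 (SE 0.068, adjusted p = 8.11e-05 in limma) in AA-supplemented knockouts against wild type. In AA-deficient knockouts it fell by 1.77 (SE 0.068, adjusted p = 8.98e-05). Its knockout mean stood at the 34.3 percentile among all genes and its wild-type mean at the 99.5 percentile. The part of the gene deleted in these mice is not given in the sources used here, so how the probes lie relative to it is not known here. Gulo encodes gulonolactone oxidase, which catalyses the last step of AA synthesis. It was at 2.04 ± 0.015 in AA-deficient knockouts, 2.05 ± 0.096 in AA-supplemented knockouts and 1.99 ± 0.065 in wild type. It passed neither between the knockouts (adjusted p = 0.982) nor in AA-deficient (adjusted p = 0.727) or AA-supplemented knockouts (adjusted p = 0.786) against wild type. Of 11 genes tested that neighbour Rgn on the X chromosome, 0 passed in any comparison with limma. Adjusted over the list alone, 1 gene was lower in AA-deficient knockouts than in wild type. This list did not pass camera between the knockouts (adjusted p = 0.640) or in AA-deficient (adjusted p = 0.336) and AA-supplemented knockouts (adjusted p = 0.471) against wild type.

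**Figure D1:**
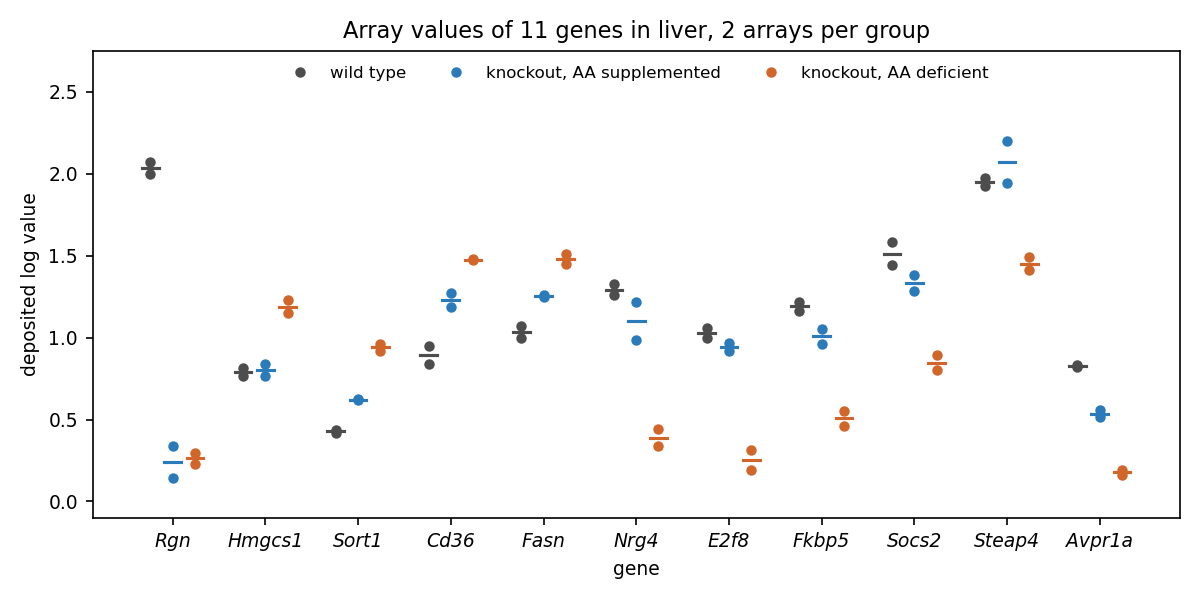
Deposited log values of 11 genes on each of the 6 liver arrays, by gene. Points are single arrays and short bars are group means of 2 arrays for wild type, AA-supplemented and AA-deficient knockouts; Rgn lies near 2.03 in wild type and near 0.24 and 0.26 in the knockouts, while E2f8 lies at 0.25 in AA-deficient knockouts against 0.94 and 1.03 in the other groups.

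The comparison of AA-deficient with AA-supplemented knockouts holds genotype constant and varies the supply of AA. The water with AA also held EDTA, and whether the other groups received EDTA is not given in the sources used here, so the supply of both may differ. Hmgcs1, the cytosolic HMG-CoA synthase at the entry to cholesterol synthesis, rose from 0.80 ± 0.054 to 1.19 ± 0.058 (difference 0.39, SE 0.049, 2.43-fold, adjusted p = 0.0405 in limma). Nrg4, an epidermal growth factor family ligand, fell from 1.10 ± 0.16 to 0.39 ± 0.074 (5.20-fold lower, adjusted p = 0.0263), and E2f8, an E2F-family transcriptional repressor, fell from 0.94 ± 0.035 to 0.25 ± 0.088 (difference -0.69, SE 0.053, adjusted p = 0.0193). Fkbp5, a co-chaperone of steroid receptors, fell from 1.01 ± 0.068 to 0.51 ± 0.068 (3.16-fold lower, adjusted p = 0.0263). Steap4, a metalloreductase and acute phase gene, fell from 2.07 ± 0.18 to 1.45 ± 0.055 (4.19-fold lower, adjusted p = 0.0405).

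In all, 30 genes passed, 6 higher and 24 lower, and 1454 had an unadjusted p under 0.05 against 733 by chance. Of these 1454, 789 were higher and 665 lower, the opposite balance. With eBayes with a trend 66 rose and 88 fell, and with a trend and robust fit 83 and 94. The other rises were Themis, known from thymocyte selection, by 0.57 (SE 0.067), Meig1 by 0.53 (SE 0.061) and Lgals1, which encodes galectin-1, by 0.40 (SE 0.051). Sort1, the sorting receptor sortilin, rose by 0.32 (SE 0.040) and Tbc1d31 by 0.31 (SE 0.043). Among genes of immune signalling, Tifa, an adaptor of TRAF proteins, changed by -0.53 (SE 0.055). C5ar1, the receptor of complement C5a, changed by -0.47 (SE 0.042) and the chemokine Ccl6 by -0.44 (SE 0.049). Socs2, an inhibitor of growth hormone and cytokine signalling, changed by -0.49 (SE 0.062). The changes were -0.45 (SE 0.045) for Scara5, a ferritin receptor, -0.52 (SE 0.067) for Plscr1, a phospholipid scramblase, and -0.36 (SE 0.041) for the vasopressin receptor Avpr1a. The zinc finger gene Zfp9 changed by -0.51 (SE 0.070) and Fndc3b by -0.42 (SE 0.046). The 30 genes had a median absolute difference of 0.43, and 29 exceeded 2-fold. Groups did not overlap for 37.3% of all genes tested, against 33.3% by chance.

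Genes of cholesterol synthesis were higher together in AA-deficient than in AA-supplemented knockouts. All 20 measured members were higher, with a median difference of 0.19 (1.55-fold). Over all genes 1 rose, and adjusted over the list alone 15 rose. The list passed camera (adjusted p = 3.60e-14), and had an adjusted p = 0.485 with an estimated correlation. Besides Hmgcs1, the methylsterol oxidase Msmo1 differed by 0.31 (SE 0.063, adjusted p = 0.132) and the sterol sensor Insig1 by 0.29 (SE 0.057, adjusted p = 0.125). Dhcr7, of the last step of the pathway, differed by 0.18 (SE 0.041, adjusted p = 0.178). Moving beside this list, 17 circadian clock genes had a median absolute difference of 0.068. Random lists matched on mean value had a median of 0.040 and a 95th percentile of 0.064. Of the clock genes, 0 passed over all genes in limma, and 1 higher and 1 lower passed adjusted over the list alone. As a list with a direction they passed neither camera (adjusted p = 0.356) nor camera with an estimated correlation (adjusted p = 0.783).

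Fatty acid and triglyceride synthesis had 17 of 21 members higher in AA-deficient than in AA-supplemented knockouts, with a median of 0.061. In limma 0 passed over all genes, and 7 rose and 1 fell adjusted over the list alone. As a list they passed camera (adjusted p = 1.23e-05), and had an adjusted p = 0.480 with an estimated correlation. Its members of smallest p did not pass over all genes. Srebf1, the SREBP-1 transcription factor, was at 0.40 (SE 0.071, adjusted p = 0.104) and Thrsp at 0.28 (SE 0.054). The elongase Elovl5 was at 0.29 (SE 0.057) and fatty acid synthase, Fasn, at 0.23 (SE 0.045). The median of the list was 0.040 without AA-deficient array 1, 0.039 without AA-supplemented array 1 and 0.093 without AA-supplemented array 2. Nrf2 targets and glutathione genes had 13 of 19 higher and a median of 0.12. Over all genes 0 passed, and 6 rose and 1 fell over the list alone. Camera called the list (adjusted p = 4.07e-04), and had an adjusted p = 0.480 with an estimated correlation. Aldehyde oxidase Aox1 was at 0.27 (SE 0.041), the exporters Abcc4 at 0.29 (SE 0.053) and Abcc3 at 0.24 (SE 0.048), and heme oxygenase Hmox1 at -0.21 (SE 0.041).

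Acute phase genes, which the liver transcribes in inflammation, were lower in AA-deficient knockouts for 25 of 26 members, with a median of -0.19. Over all genes 1 fell, Steap4, and 12 fell adjusted over the list alone. The list as a whole passed camera (adjusted p = 8.66e-15), and had an adjusted p = 0.485 with an estimated correlation. Lcn2 (lipocalin 2) differed by -0.79 (SE 0.13, adjusted p = 0.0830), the serum amyloid gene Saa2 by -0.78 (SE 0.14, adjusted p = 0.104) and the orosomucoid gene Orm2 by -0.50 (SE 0.071, adjusted p = 0.0519). Without AA-supplemented array 2 the median of the list was -0.12. All 18 genes of the unfolded protein response were lower (median -0.10), with 0 past the threshold over all genes and 4 lower over the list alone. This list passed camera (adjusted p = 5.56e-08), and had an adjusted p = 0.485 with an estimated correlation. Xbp1 was at -0.18 (SE 0.045), Dnajb11 at -0.18 (SE 0.052; -0.12 without AA-supplemented array 1) and Sdf2l1 at -0.17 (SE 0.047). All 11 heat shock genes were lower (median -0.13), with 0 past the threshold over all genes and 5 lower over the list alone. They passed camera (adjusted p = 8.92e-07), and had an adjusted p = 0.485 with an estimated correlation. Hsp90aa1 was at -0.21 (SE 0.048) and Hsph1 at -0.20 (SE 0.056).

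A further 4 lists passed camera with small medians and lost that call without single arrays or, for 3 of them, under other settings, and 0 of their members passed over all genes in limma. Liver endothelial markers were higher for 11 of 13 genes (median 0.066), with 0 past the threshold over the list alone. Their adjusted p was 0.00890, and the adjusted p = 0.589 with an estimated correlation. Kdr was at 0.12 (SE 0.044), Tek at 0.14 (SE 0.052; 0.071 without AA-supplemented array 2) and Eng at 0.11 (SE 0.040). Without AA-deficient array 2 the median of this list was 0.038 (adjusted p = 0.176), and without AA-supplemented array 2 it was 0.058 (adjusted p = 0.108). Bile acid genes were higher for 15 of 21 (median 0.036), with 1 higher over the list alone. Their adjusted p was 0.0274, and the adjusted p = 0.570 with an estimated correlation. The sterol exporter Abcg8 was at 0.24 (SE 0.054) and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at 0.56 (SE 0.19). Genes of AA synthesis and transport were higher for 9 of 11 (median 0.025), with 1 higher over the list alone. Their adjusted p was 0.0320, and the adjusted p = 0.589 with an estimated correlation. The AA transporters Slc23a2 and Slc23a1 were at 0.19 (SE 0.040) and 0.09 (SE 0.040). Fatty acid oxidation genes were higher for 18 of 26 (median 0.025), with 1 higher over the list alone. Their adjusted p was 0.0320, and the adjusted p = 0.654 with an estimated correlation. The fatty acid transporter Cd36 was at 0.24 (SE 0.052). The calls of these last lists were lost without AA-deficient array 1, with adjusted p of 0.0763 for bile acid genes, 0.167 for AA genes and 0.163 for fatty acid oxidation. In the same order they were 0.111, 0.144 and 0.0860 without AA-supplemented array 1, and 0.0502, 0.0502 and 0.108 without AA-supplemented array 2. The medians of bile acid genes were 0.026, 0.0097 and 0.062 without these arrays in turn, those of AA genes 0.013, 0.090 and 0.061 (and 0.061 without AA-deficient array 2), and those of fatty acid oxidation 0.011, 0.029 and 0.045. With a filter at the 50th percentile they were 0.0519, 0.0508 and 0.0633. Removal of the trend on span gave 0.0705 for both bile acid genes and fatty acid oxidation. The latter was also at 0.0562 after quantile normalisation and 0.0707 after cyclic loess normalisation.

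The 30 genes depended on single arrays: 1 passed without AA-deficient array 1, 7 without AA-deficient array 2 and 46 without AA-supplemented array 1. In limma 0 passed without AA-supplemented array 2, wild-type array 1 or wild-type array 2, without a filter on dim genes (1550 at an unadjusted p under 0.05), or with only the 4 arrays compared. The fits without either wild-type array and with only the 4 arrays compared are one and the same for this comparison, as a single array adds nothing to the spread. Quantile normalisation left 1 higher and 13 lower, centring on the median 1 and 12, cyclic loess 1 and 12, and removal of the trend on gene span 0 and 11.

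The comparison of AA-deficient knockouts with wild type combines the loss of the gene with the loss of AA. Cd36 rose from 0.89 ± 0.074 in wild type to 1.47 ± 0.0056 (difference 0.58, SE 0.052, 3.81-fold, adjusted p = 0.00478 in limma), and lipoprotein lipase, Lpl, from 0.68 ± 0.14 to 1.42 ± 0.095 (5.42-fold, adjusted p = 0.0104). Fasn rose from 1.03 ± 0.052 to 1.48 ± 0.042 (2.79-fold, adjusted p = 0.00597). Nrg4 fell from 1.29 ± 0.048 to 0.39 ± 0.074 (8.04-fold lower, adjusted p = 0.00400), and Avpr1a from 0.83 ± 0.0095 to 0.18 ± 0.023 (difference -0.65, SE 0.041, adjusted p = 0.00219). Slc10a2, the apical sodium-dependent bile acid transporter, fell by 0.74 (SE 0.060, 5.47-fold lower, adjusted p = 0.00331).

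In this comparison 679 genes passed, 452 higher and 227 lower (66.6% higher), with a median absolute difference of 0.26, and 215 exceeded 2-fold. Groups did not overlap for 54.5% of genes, against 33.3% by chance. The largest rises also took in Igfbp1, an insulin-like growth factor binding protein, by 0.77 (SE 0.16), Themis by 0.68 (SE 0.067) and Fam13a by 0.62 (SE 0.093). The teneurin gene Tenm3 rose by 0.61 (SE 0.056), Erbb4, a receptor of neuregulins, by 0.59 (SE 0.076) and the nuclear noncoding RNA Malat1 by 0.59 (SE 0.12; 0.38 without wild-type array 1). Nebulin, Neb, rose by 0.57 (SE 0.079), the imprinted antisense RNA Airn by 0.56 (SE 0.056), Lrtm1 by 0.55 (SE 0.059) and the immediate early gene Egr1 by 0.52 (SE 0.099). Among the largest falls, E2f8 changed by -0.77 (SE 0.053), Lcn2 by -0.69 (SE 0.13), Fkbp5 by -0.68 (SE 0.054) and Saa2 by -0.68 (SE 0.14; -0.43 without AA-deficient array 1). Socs2 changed by -0.66 (SE 0.062), Plscr1 by -0.59 (SE 0.067), the acyltransferase gene Acnat2 by -0.58 (SE 0.054) and the dehydrogenase gene Dhrs9 by -0.55 (SE 0.083). Of the 450 rising genes with a known span, 236 (52.4%) belonged to the 20% of tested genes with the longest span in the genome, 63.3 kb and up. Of the 227 falling genes, 28 did. Across genes, which are not independent replicates, the difference correlated with span at a Spearman coefficient of 0.236, against 0.20 in AA-supplemented knockouts against wild type and 0.126 between the knockout groups. The longest 20% had a median difference of 0.039 here, 0.026 and 0.013 in the same order.

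**Figure D2:**
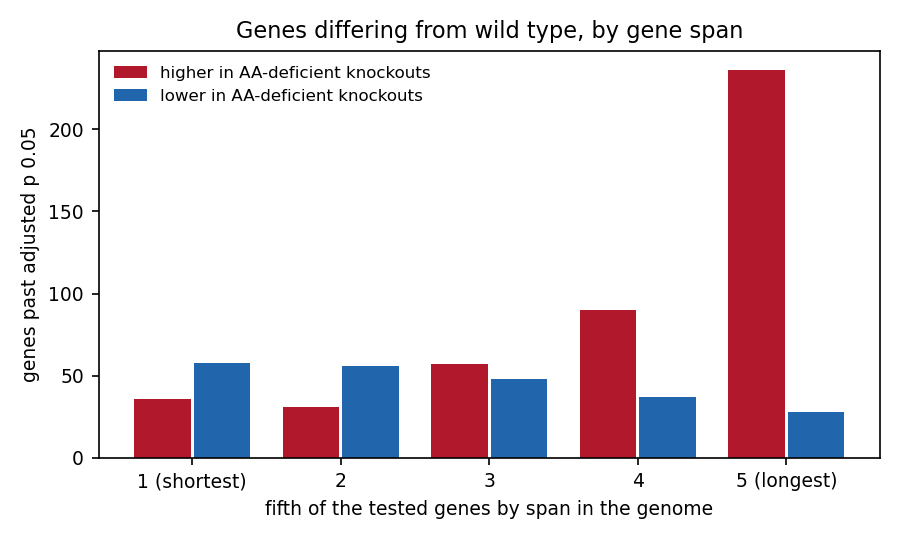
Number of genes past an adjusted p of 0.05 (vertical axis) in AA-deficient knockouts against wild type, for tested genes divided into equal parts by their span in the genome (horizontal axis, shortest to longest). Red bars are higher and blue bars lower genes; the group of longest genes holds 236 higher and 28 lower, and the group of shortest genes 36 and 58.

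In fatty acid and triglyceride synthesis 19 of 21 members were higher than in wild type (median 0.11), 5 rose over all genes and 9 adjusted over the list alone. The list passed camera (adjusted p = 5.76e-05), and had an adjusted p = 0.609 with an estimated correlation. Srebf1 rose by 0.46 (SE 0.071), Mlxipl, the carbohydrate response factor ChREBP, by 0.30 (SE 0.050) and acetyl-CoA carboxylase, Acaca, by 0.26 (SE 0.041). In fatty acid oxidation 20 of 26 were higher (median 0.058), 2 rose over all genes and 6 over the list alone. It passed camera (adjusted p = 0.00497), and had an adjusted p = 0.759 with an estimated correlation. The genes that rose over all genes were Cd36 and the peroxisomal enzyme gene Ehhadh, the latter by 0.24 (SE 0.047). Without wild-type array 2 the median of that list was 0.013 (adjusted p = 0.117).

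Among bile acid genes 16 of 21 were higher than in wild type (median 0.098), 3 rose over all genes, and 4 rose and 1 fell over the list alone. As a list they passed camera (adjusted p = 0.00776), and had an adjusted p = 0.759 with an estimated correlation. The sterol exporter genes Abcg8 and Abcg5 rose by 0.40 (SE 0.054) and 0.26 (SE 0.058), and the sterol 12-hydroxylase Cyp8b1 by 0.37 (SE 0.052). Without wild-type array 2 the median was 0.082 (adjusted p = 0.0800), and with the trend on gene span removed it was 0.053 (adjusted p = 0.150). In cholesterol synthesis 15 of 20 were higher (median 0.064), 1 rose over all genes, Hmgcs1 by 0.40 (SE 0.049), and 2 rose over the list alone. Camera called the list (adjusted p = 0.0424), and had an adjusted p = 0.859 with an estimated correlation. This call was lost without AA-deficient array 1 (median 0.030, adjusted p = 0.548) or wild-type array 2 (median 0.033, adjusted p = 0.411). Without either AA-supplemented array the median stayed at 0.064, with an adjusted p of 0.0518, and without AA-deficient array 2 it was 0.10. Median centring (0.0517) also ended it, as did a fit of only the 4 arrays compared (0.0518), which is the same fit as that without either AA-supplemented array. Lipoprotein and lipid transport genes did not pass camera (adjusted p = 0.348). Of these, Lpl and the receptor gene Lrp1, by 0.48 (SE 0.069), rose and Apoa4 changed by -0.46 (SE 0.075), while 4 rose and 2 fell over the list alone.

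Nrf2 targets and glutathione genes had 14 of 19 members higher than in wild type (median 0.094). Over all genes 4 rose and 1 fell, and over the list alone 7 rose and 2 fell. The list as a whole passed camera (adjusted p = 0.00497), and had an adjusted p = 0.609 with an estimated correlation. Abcc3 rose by 0.43 (SE 0.048), Aox1 by 0.36 (SE 0.041), Abcc4 by 0.26 (SE 0.053) and the epoxide hydrolase gene Ephx1 by 0.25 (SE 0.042). The member that fell, named after its value was seen, was the sulfiredoxin gene Srxn1 at -0.33 (SE 0.068). Glucose metabolism had 13 of 15 higher (median 0.075), and 3 rose over all genes and over the list alone. It passed camera (adjusted p = 0.00502), and had an adjusted p = 0.759 with an estimated correlation. The rises were those of Igfbp1, the insulin receptor substrate gene Irs1, by 0.27 (SE 0.047), and the transcription factor gene Foxo1, by 0.19 (SE 0.042). Its median was 0.12 without wild-type array 1, 0.049 without wild-type array 2 (adjusted p = 0.0800) and 0.029 with the trend on gene span removed (adjusted p = 0.0684).

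The list of AA synthesis and transport did not pass in AA-deficient knockouts against wild type (adjusted p = 0.405). Its median was 0.045 and its mean -0.088, since it holds Rgn. Besides Rgn only the AA transporter gene Slc23a2 changed over all genes, by 0.34 (SE 0.040, adjusted p = 0.00777), and 4 rose and 1 fell over the list alone. The list did not pass in AA-supplemented knockouts either (adjusted p = 0.697), where Rgn was its 1 member past the threshold over all genes and 1 rose and 1 fell over the list alone. Cytochrome P450 and xenobiotic genes did not pass as a list (adjusted p = 0.126). Of these, Cyp3a25 rose by 0.20 (SE 0.044) and the nuclear receptor gene Nr1i3 (CAR), named after its value was seen, by 0.26 (SE 0.058). Cyp2b10 changed by -0.51 (SE 0.11) and the sulfotransferase gene Sult1d1 by -0.20 (SE 0.044). Over the list alone 3 rose and 2 fell.

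Acute phase genes were lower than in wild type for 22 of 26 members (median -0.10). Over all genes 3 fell, Lcn2, Saa2 and Steap4, the last at -0.50 (SE 0.079), and 8 fell over the list alone. The list passed camera (adjusted p = 1.30e-04), and had an adjusted p = 0.802 with an estimated correlation. In the unfolded protein response 15 of 18 were lower (median -0.12), 4 fell over all genes and 7 over the list alone. It passed camera (adjusted p = 5.86e-05), and had an adjusted p = 0.759 with an estimated correlation. Creld2 changed by -0.49 (SE 0.096), Dnajb11 by -0.32 (SE 0.052), Manf by -0.27 (SE 0.055) and Xbp1, a transcription factor of this response, by -0.21 (SE 0.045). Heat shock genes were lower for 10 of 11 (median -0.099). Over all genes 2 fell, Hsp90aa1 at -0.23 (SE 0.048) and the mitochondrial chaperonin gene Hspe1 at -0.20 (SE 0.045), and 1 rose and 5 fell over the list alone. As a list they passed camera (adjusted p = 0.00856), and had an adjusted p = 0.759 with an estimated correlation. Without AA-deficient array 2 the median of the heat shock list was -0.057 (adjusted p = 0.0720).

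Without wild-type array 1 the 679 genes came down to 1, Rgn, and likewise without wild-type array 2, while 140 passed without AA-deficient array 1, 88, 45 higher and 43 lower, without AA-deficient array 2 and 1031 without either AA-supplemented array. Leaving out either AA-supplemented array is the same fit here as only the arrays compared, since a single array adds nothing to the spread. Quantile normalisation gave 439 higher and 305 lower (59.0% higher), removal of the trend on gene span 347 and 265 (56.7%), no filter on dim genes 173 in all, and the replicate number as a block 163.

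AA-supplemented knockouts and wild type differ in genotype while AA was supplied to the knockouts, in water with EDTA. Rgn was the 1 gene that passed, lower, against 1557 genes with an unadjusted p under 0.05, 994 higher and 563 lower. The genes of next smallest p did not pass. Zmiz1, a transcriptional coactivator, was at 0.39 (SE 0.044) and Kmt2d, a histone methyltransferase, at 0.41 (SE 0.051), each with an adjusted p of 0.109 in limma. Ms4a4a was at -0.43 (SE 0.054), Airn at 0.44 (SE 0.056) and Tacc2 at 0.40 (SE 0.054). Further values were -0.29 (SE 0.041) for Avpr1a, 0.28 (SE 0.042) for C5ar1, 0.31 (SE 0.046) for Kmt2a and 0.33 (SE 0.049) for Prg4. Of the lipid genes, Cd36 differed by 0.34 (SE 0.052), Lrp1 by 0.45 (SE 0.069), Lpl by 0.43 (SE 0.090), Fasn by 0.22 (SE 0.045) and Acaca by 0.23 (SE 0.041), with adjusted p between 0.135 and 0.190. With 2 arrays per group, values that did not pass cannot be read as absent differences. Removal of AA-supplemented array 1 left 7 genes, eBayes with a trend gave 94 and with a trend and robust fit 116, the replicate block 3 and removal of the trend on gene span 2.

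Cholesterol synthesis genes were lower in AA-supplemented knockouts than in wild type for 19 of 20 members (median -0.10). In limma 0 passed over all genes, and 5 fell adjusted over the list alone. Camera called the list (adjusted p = 4.88e-06), and had an adjusted p = 0.833 with an estimated correlation. Msmo1 was at -0.25 (SE 0.063) and the isopentenyl isomerase gene Idi1 at -0.21 (SE 0.058). The sterol demethylase gene Cyp51 was at -0.21 (SE 0.056) and lanosterol synthase, Lss, at -0.17 (SE 0.048; -0.11 without AA-supplemented array 2). The median of the list was -0.046 without wild-type array 1 and -0.16 without wild-type array 2.

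The other 4 lists past camera in this comparison had 0 members past the threshold over all genes in limma, and each had an adjusted p = 0.833 with an estimated correlation. Glucose metabolism was higher for 14 of 15 (median 0.067, adjusted p = 0.00544), with 0 past the threshold over the list alone. Acute phase genes were higher for 23 of 26 (median 0.074, adjusted p = 0.0152), male-biased liver genes for 13 of 15 (median 0.059, adjusted p = 0.0159) and immediate early genes for 9 of 12 (median 0.077, adjusted p = 0.0159). Over the list alone 1 gene was higher in each of these. Orm2 was at 0.37 (SE 0.071) and Saa3 at 0.58 (SE 0.21), or 0.87 without AA-supplemented array 1 and 0.28 without AA-supplemented array 2. The male-biased Susd4 was at 0.22 (SE 0.047), Foxo1 at 0.13 (SE 0.042) and Egr1 at 0.58 (SE 0.099). These 4 calls rested on single arrays. Without AA-supplemented array 2 the median of the acute phase list was -0.019 and that of male-biased genes -0.00047, the other direction. The adjusted p was then 0.998 and 0.693, 0.107 for glucose metabolism and 0.121 for immediate early genes. The medians of the last 2 were 0.049 and 0.075. Without AA-supplemented array 1 the medians were 0.14, 0.12, 0.11 and 0.14 for acute phase, male-biased, glucose and immediate early genes. Without wild-type array 1 the medians were 0.063 for acute phase (adjusted p = 0.0747) and 0.075 for male-biased genes (adjusted p = 0.0796), and 0.11 and 0.14 for glucose and immediate early genes. Without wild-type array 2 they were 0.038 for glucose metabolism (adjusted p = 0.164) and 0.056 for immediate early genes (adjusted p = 0.427). Removal of the trend on gene span left medians of 0.045, 0.033 and 0.031 for acute phase, male-biased and glucose genes, with adjusted p of 0.0626, 0.0650 and 0.0626. For acute phase genes quantile normalisation left 0.026 (adjusted p = 0.0707) and cyclic loess 0.040 (adjusted p = 0.0519).

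**Figure D3:**
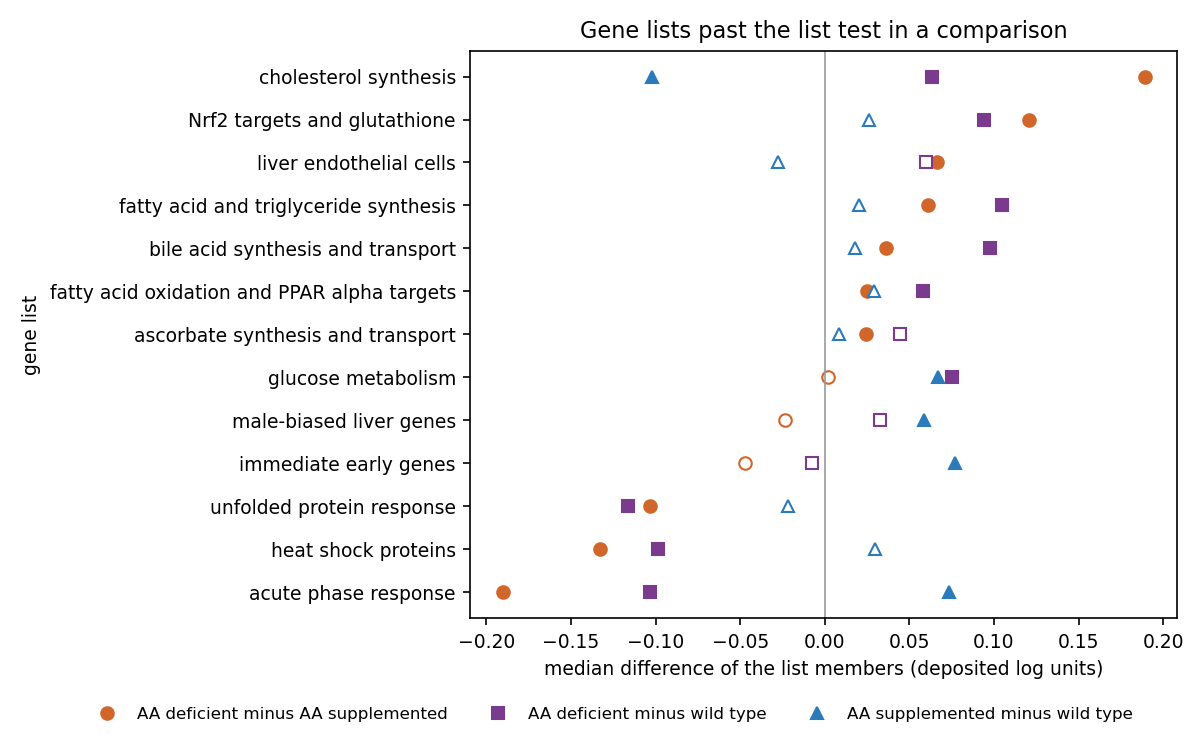
Median difference of the members of 13 gene lists (horizontal axis, deposited log units) in the 3 comparisons, for lists past camera in at least 1 of them. Circles, squares and triangles stand for the comparisons, filled where the list passed camera and open where it did not; cholesterol synthesis lies at 0.19, 0.064 and -0.10, and acute phase genes at -0.19, -0.10 and 0.074, the last of which turned to -0.019 without AA-supplemented array 2.

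Of the 30 genes that separated the knockouts by AA supply, 28 also passed in the same direction against wild type, 6 higher and 22 lower in AA-deficient knockouts. They included Nrg4, E2f8, Themis, Fkbp5, Socs2, Steap4, Plscr1, Tifa, at -0.53 and -0.54 against the supplemented and wild-type groups, Zfp9 and Avpr1a. Independent lists of these sizes would share 0.557 genes, and 0 were shared on average in 100 simulations of unchanged groups with the same shared arrays. The first value leaves out the shared arrays, and the other is fixed by how few genes limma calls between unchanged groups, so neither is a baseline for the 28. Over all 14662 genes the differences of both comparisons correlated at 0.687, against 0.501 in the simulations, with a covariance of 0.00594 against 0.00203, a difference of 0.00391. With the AA-deficient arrays split, 1 in each comparison and chosen after seeing the data, the correlations were 0.411 and 0.440 for the 2 ways, against -0.0030 and -0.0029 in simulations. The covariances were then 0.00420 and 0.00452. The number shared was 1 without AA-deficient array 1, 6 without AA-deficient array 2, and 0 without AA-supplemented array 2, wild-type array 1 or wild-type array 2, where limma called 0 genes between the knockouts.

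Between the comparisons of either knockout group with wild type, 1 gene was shared, Rgn, against 0.0155 for independent lists, with the same limit. The correlation over genes was 0.672, against 0.498 in simulations that shared the wild-type arrays, and the covariance 0.00570 against 0.00202, a difference of 0.00368. Of the 678 other genes that separated AA-deficient knockouts from wild type, 28 also differed past the threshold between the knockout groups. With the wild-type arrays split in the same way the correlations were 0.405 and 0.417, against 0.0012 and 0.0016 in simulations, and the covariances 0.00406 and 0.00423. Leaving out AA-supplemented array 1 gave 4 shared genes.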

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

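The tests by quantile normalisation of the number of genes against wild type and by removal of the trend on gene span of the excess of rises were chosen only after the result was seen; the other tests below were written down before theirs.

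Probe sets without a gene symbol held calls that the gene counts leave out. Of 5315 tested, 239 passed in AA-deficient knockouts against wild type, 219 higher and 20 lower, and 84 in AA-supplemented knockouts against wild type, 83 higher and 1 lower. Between the knockout groups 0 passed in limma, with 222 at an unadjusted p under 0.05. Of 858 probe sets with several symbols, 1 passed, in AA-deficient knockouts against wild type (-0.44, SE 0.054, adjusted p = 0.0488). Most of the unnamed calls came from 2291 probe sets numbered below the first named one. Of these, 180 were higher and 4 lower (median 0.042) in AA-deficient and 74 higher and 0 lower (median 0.041) in AA-supplemented knockouts. The 3024 others gave 39 higher and 16 lower, and 9 and 1. What these probe sets measure was not analysed here, so their calls cannot be read as changes of genes.

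Cholesterol synthesis genes stood higher in AA-deficient than in AA-supplemented knockouts, with a median of 0.19. A difference in the intensity distribution of the arrays is argued against, as quantile normalisation left 97.3% of the median. So is a single array, as the lowest value, without AA-deficient array 1, was 74.8% of the full one. A difference in the time of day of tissue collection stays open, as cholesterol synthesis follows a daily rhythm. The absolute differences of the clock genes lay at the 97.1 percentile of 10000 random lists, which is what such a difference would give. The random lists were matched on mean value and not on spread. Genes that vary more for any other reason could therefore give the same percentile, and it does not single out collection time. The supply of AA, which the design varies, is a biological explanation and may act as well. Part of the 0.19 came from AA-supplemented knockouts lying below wild type (median -0.10), while AA-deficient knockouts lay above it by 0.064. A lack of AA need not be all of it. Without single arrays these medians came down to -0.046 and 0.030. No test here parts the supply of AA from collection time, food intake or the EDTA given with it.

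Acute phase genes stood lower in AA-deficient than in AA-supplemented knockouts, with a median of -0.19. Quantile normalisation left 89.6% of it, which argues against the intensity distribution as the whole cause. Without AA-supplemented array 2, the lowest of the 4 values, 65.5% was left, so no single array could account for all of it. The supplemented arrays differed from each other in some members, with Saa3 at 1.47 ± 0.42 (SD, n = 2). The supply of AA stays among the open explanations, as untested.

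In AA-deficient knockouts against wild type more genes rose than fell. Gene span and intensity distribution are argued against as the whole cause of their number, since 90.1% as many genes passed once the trend on span was removed and 110% as many after quantile normalisation. Which genes passed did depend on these steps: of the 679, only 462 were among the 612 without the trend on span, and 611 among the 744 after quantile normalisation. For the excess of rises the trend stays open, as 347 rose and 265 fell once it was removed, a ratio of 1.31, so the excess shrank but was not gone. Without AA-deficient array 2, 45 rose and 43 fell, so the excess also rested on that array.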

How the results depend on the processing

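Removal of the trend on gene span, cyclic loess normalisation, the crossed block and the split of shared arrays were chosen after seeing the data; all other alternatives were planned. The counts of genes below are given for AA-deficient against AA-supplemented knockouts (30), AA-deficient knockouts against wild type (679) and AA-supplemented knockouts against wild type (1), in this order, with genes shared by the first and the second comparison (28) and by the second and the third (1) where they moved by over 1.5 times. Without a filter on dim genes the first comparisons gave 0 (limma, 1550 at an unadjusted p under 0.05) and 173, with 0 shared. With a filter at the 50th percentile they gave 51 and 1057, with 48 shared. The filter changes the number of tests and also the spread that limma shares between genes, and the cause was not tested. Quantile normalisation gave 14 in the first, with 14 shared, median centring 13 and 12, cyclic loess 13 and 13, and removal of the trend on span 11 and 11, with 2 in the third and 2 shared by the second and the third. The cause was not tested. eBayes with a trend gave 154, 1271 and 94, with 135 and 83 shared. With a trend and robust fit the counts were 177, 1312 and 116, with 159 and 104 shared; the cause was not tested. Array weights gave 15 and 1344, with 15 shared by the first comparisons; the cause was not tested. With only the 4 arrays compared, the first gave 0 and the second 1031, with 0 shared. Leaving out either array of the group not compared is the same fit, since a single array adds nothing to the spread. The second then loses the AA-supplemented arrays, whose replicate differences had an SD of 0.104, against 0.079 in each other group. The cause was not tested further. The mean of a gene's probe sets moved no count by over 1.5 times. The planned change of the pseudocount was not run, since the values were on a log scale.

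Lists past camera numbered 10, 9 and 5 in the same order. An estimated correlation and fry each gave 0, 0 and 0, and removal of the trend on span gave 2 in the third comparison. Leaving out each array in turn gave 0 to 46, 1 to 1031 and 1 to 7 genes, 0 to 39 and 1 to 4 shared genes, and 6 to 10, 5 to 10 and 2 to 8 lists. With an array left out, its group holds a single array that is assumed to vary like the others. Of the medians of lists past camera under the alternatives, 411 kept their direction and their call, 43 kept the direction but not the call, and 2 reversed. Both reversed without AA-supplemented array 2, in AA-supplemented knockouts against wild type: acute phase genes at -0.019, in a range of -0.019 to 0.14 without single arrays, and male-biased genes at -0.00047, in a range of -0.00047 to 0.12. The cause was not tested. Of the values of named genes, 2866 kept their direction and passed either in both fits or in neither, 433 lost the call and 146 gained one. A further 6 that had not passed took the other direction, and 0 reversed a call. Most of the named genes had no call to lose outside the second comparison. In the main fit 19 of 65, 54 of 66 and 1 of 51 passed, in the order of the comparisons above. The values that lost the call numbered 197, 236 and 0 in that order.

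The labels number the arrays 1 and 2 in every group but name nothing that same-numbered arrays share. The deviations of same-numbered arrays correlated at -0.369 (AA-deficient with AA-supplemented), 0.358 (AA-deficient with wild type) and -0.284 (AA-supplemented with wild type). After quantile normalisation the values were -0.304, 0.317 and -0.206. The numbers as given therefore do not pair the samples. With the AA-supplemented numbers crossed all 3 would be positive, as a factor shared across the groups would give. The distributions of the values divide the arrays in this crossed way too. The range from the 25th to the 75th percentile was 0.560, 0.532 and 0.560 on AA-deficient array 1, AA-supplemented array 2 and wild-type array 1. On AA-deficient array 2, AA-supplemented array 1 and wild-type array 2 it was 0.607, 0.618 and 0.611. Arrays of different groups thus shared a feature of their distributions, which the main fit does not model. Its source is not known here. With the replicate number as a block, the counts were 4, 163 and 3 genes, with 3 and 3 shared, and 10, 9 and 7 lists. With the numbers of the AA-supplemented arrays crossed, the counts were 75, 1561 and 1 genes, with 69 shared by the first comparisons, and 8, 9 and 5 lists. Signal over background was not used here, so the filter on the mean value stands in for it.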

Other observations

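The lists of glucocorticoid and growth hormone targets, and the members named in the paragraphs on further lists, were chosen only after the result was seen.

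Collagens with their processing enzymes, hypoxia-inducible factor targets and carnitine synthesis hold enzymes, or are controlled by enzymes, that use AA as a cofactor. Between AA-deficient and AA-supplemented knockouts, 0 of 17 collagen genes passed in limma over all genes and over the list alone. Their median was 0.0039 and their mean -0.0085 (camera adjusted p = 0.799). Of the 6 carnitine genes 0 passed by either count (median 0.058). That list did not pass camera (adjusted p = 0.268). Of 15 hypoxia genes 0 passed over all genes, and 1 rose and 1 fell over the list alone. Their median was -0.0078 and their mean 0.0074 (adjusted p = 0.729). Pfkfb3, a regulator of glycolysis, was at -0.36 (SE 0.060, adjusted p = 0.0889) and Ndrg1 at 0.20 (SE 0.049, adjusted p = 0.209). Against wild type 0 members of these lists passed over all genes in either knockout group. The camera adjusted p of collagen, carnitine and hypoxia genes was 0.206, 0.606 and 0.618 in AA-deficient knockouts and 0.0539, 0.801 and 0.706 in AA-supplemented knockouts. Antioxidant enzymes gave 0 of 15 over all genes and over the list alone in each comparison. Their adjusted p was 0.629 between the knockouts, 0.695 in AA-deficient and 0.266 in AA-supplemented knockouts against wild type.

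Markers of most cell types did not pass camera as lists, which does not show that they stayed the same. The camera adjusted p between the knockouts was 0.923 for hepatocytes, macrophages with Kupffer cells, and lymphocytes. It was 0.605 for stellate cells with fibroblasts and for adipocytes, 0.834 for cholangiocytes, 0.135 for neutrophils and 0.356 for pancreatic acinar cells. Against wild type the lowest adjusted p of these lists was 0.327 in AA-deficient knockouts (macrophages and Kupffer cells) and 0.242 in AA-supplemented knockouts (stellate cells and fibroblasts). Against wild type macrophage and Kupffer markers were higher for 14 of 15 in AA-deficient (median 0.042) and 13 of 15 in AA-supplemented knockouts (median 0.029). Hepatocyte markers were higher for 11 of 13 in both (medians 0.043 and 0.051). Over all genes limma called 0 members of these lists except in AA-deficient knockouts against wild type, where adipocyte genes moved apart. Pparg, a nuclear receptor of lipid storage, rose by 0.47 (SE 0.043, adjusted p = 0.00478). Cidec, which encodes a lipid droplet protein, changed by -0.47 (SE 0.046, adjusted p = 0.00520). The endothelial scavenger receptor gene Stab2 rose by 0.24 (SE 0.045) in that comparison, where the endothelial list did not pass (adjusted p = 0.170).

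Further lists passed camera in none of the comparisons while single members changed in AA-deficient knockouts against wild type. Iron genes (adjusted p = 0.123) held rises of the ferrireductase gene Steap3 by 0.29 (SE 0.042) and the iron exporter gene Slc40a1 by 0.21 (SE 0.043). Among female-biased genes (adjusted p = 0.327), Cyp17a1, a steroid hydroxylase, changed by -0.49 (SE 0.055). Cell cycle genes (adjusted p = 0.727) had a mean of -0.022 and a median of 0.0085. Of these, Rrm2, of deoxynucleotide synthesis, changed by -0.32 (SE 0.041) and cyclin D1, Ccnd1, by -0.30 (SE 0.042). Among Atf4 targets (adjusted p = 0.727) the amino acid transporter gene Slc38a2 rose by 0.24 (SE 0.047). Among clock genes (adjusted p = 0.170), Per1 rose by 0.28 (SE 0.042), Nr1d1 by 0.32 (SE 0.062) and Ciart changed by -0.39 (SE 0.078). Targets of p53 and interferon genes gave 0 over all genes in limma and over the list alone (adjusted p = 0.877 and 0.951).

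Fkbp5 and Socs2, which fell in AA-deficient against AA-supplemented knockouts, are known targets of the glucocorticoid receptor and of growth hormone. Lower activity of either may lie behind the falls, and each was tested on other targets, without Fkbp5 and Socs2. The 22 other glucocorticoid targets, 14 of them also in another list, had a median difference of -0.032, with 13 lower and 9 higher. Over all genes 0 passed in limma (camera p = 0.0959, and p = 0.346 with an estimated correlation). The 16 other growth hormone targets, 8 of them also in another list, had a median of -0.0030, with 8 higher and 8 lower. Their camera p was 0.921. Members going both ways decide neither hypothesis between the knockouts. Against wild type, where Fkbp5 and Socs2 changed by -0.68 and -0.66, 11 of the 16 growth hormone targets were higher (median 0.054). Their camera p was 0.0441, and p = 0.216 with an estimated correlation. Stat5b (0.24) and Cyp2u1 (0.23) rose over all genes, while Cish (-0.19) and Socs3 (-0.11) were among the 5 lower. The test did not take account of whether growth hormone raises or lowers a member, and Stat5b encodes a transducer of its signal. The tally therefore does not decide this hypothesis. In AA-supplemented knockouts against wild type 14 of the 16 were higher (median 0.066), a value that shares its wild-type arrays with that of AA-deficient knockouts. There the camera p was 0.00396, and p = 0.111 with an estimated correlation. The glucocorticoid targets had a median of -0.045 against wild type, with 13 of 22 lower. Their camera p was 0.393. Over all genes Igfbp1 (0.77) and Per1 (0.28) rose and Lcn2 (-0.69) fell, so members past the threshold went both ways. Both hypotheses stay open.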
